A study of Mus musculus with 6 samples.

How the data were processed

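Poly(A)-selected RNA of mouse bone-marrow-derived macrophages was measured by RNA sequencing on an Illumina NovaSeq. Per the labels, marrow cells of 6-week-old male C57BL/6 mice were cultured for 6 days in medium with 20% serum and 30% L-929-conditioned medium, a source of the growth factor M-CSF. They were then kept for 6 h with PBS or with extracellular vesicles (EVs) of the mould Aspergillus flavus at 20 µg per well. The EV groups are labelled LD-F1 and LD-F1_b, and the sample titles call each of these a strain. What the suffix stands for is not given in the sources used here. The 3 groups hold 2 biological replicates each, 6 libraries in all.

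The deposited table holds whole-number counts of reads per gene for the 6 libraries, not normalised. Per the submitters' processing notes, the authors used fastp, HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 with the mouse build GRCm39. The gene identifiers of the table are those of the C57BL/6NJ strain annotation for 41096 of the 41972 entries, and the remaining 876 are loci assembled from the reads. The last gene on chromosome 1 ends at position 208807027, beyond the end of that chromosome in GRCm39, so positions are given as the table has them and are taken to be those of the C57BL/6NJ assembly. The strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes with close copies, such as Ifi204 and Ifi205, Ifit1, Hspa1b, H2-K1, Ppia and the ribosomal protein genes, are therefore uncertain, as are genes that overlap another on the opposite strand. Of all entries, 20461 are annotated as protein coding, 11563 are named by an identifier alone and 22255 had at least 1 count. The table has 0 entries that lack an identifier or hold summary counts, so no entry was left out of the total counts given below. Of its per-sample columns, 0 stayed unmatched.

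Total counts per library were 13722215 and 14589976 (LD-F1), 14540448 and 14618148 (LD-F1_b) and 14702478 and 15277997 (PBS). A floor of 3 counts in a library corresponds to 0.189 to 0.225 CPM (counts scaled to a common total). Floors and 95% intervals of ratios cover counting error only, since the reads carry no molecular identifiers. The 10 most abundant genes took 4.10% to 4.51% of the counts of a library and the assembled loci 1.87% to 2.22%. Pearson's r of log2 CPM (prior count 2) between replicates was 0.9842 for LD-F1, 0.9885 for LD-F1_b and 0.9910 for PBS. The LD-F1 replicates correlated less with each other than with the LD-F1_b libraries (0.9846 to 0.9862), and they lay apart on the second principal component (29.3 and -21.6). Counts of the replicates differed by more than counting error, with a chi-square per degree of freedom of 18.4, 5.67 and 3.20 in that order, so none was a copy of another. Between the LD-F1 replicates the log2 difference followed gene length across 7759 genes (Spearman's rho = -0.53, against -0.25 for LD-F1_b and -0.014 for PBS; genes are not independent replicates).

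Differential expression was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 12740 with 99.89% to 99.92% of the counts of a library. Totals for scaling were taken over these genes, and libraries were scaled by TMM factors of 0.965 to 1.04. All 6 libraries entered 1 fit with a mean per group and 3 residual degrees of freedom, with robust estimation of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in that comparison, and "higher", "rose", "lower" and "fell" are used for called genes. Errors of log2 fold changes are standard errors (SE) computed back from the test, and errors of CPM are standard deviations (SD) over the 2 replicates. The 3 comparisons were LD-F1 EVs with PBS, LD-F1_b EVs with PBS, and LD-F1_b EVs with LD-F1 EVs.

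Before the data were examined, 52 gene lists were fixed, covering pathways and markers of the cell types a marrow culture could hold. The 42 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the 126 tests. With an estimated correlation, 10 of the 24 lists called for LD-F1 EVs held, 6 of the 24 called for LD-F1_b EVs and 7 of the 19 called between the EV groups. Those 10 were proinflammatory cytokines, chemokines, NF-kB, type I interferon, interferon gamma, anti-inflammatory regulators, NRF2, immediate early genes, the stress response and the G2 and M phase. The 6 were cytokines, chemokines, NF-kB, anti-inflammatory regulators, immediate early genes and the stress response, and the 7 were cytokines, chemokines, NF-kB, both interferon lists, anti-inflammatory regulators and the G2 and M phase. The directional fry test, which asks whether the members of a list move 1 way on balance, called 34, 30 and 19 lists. Genes were named by a rule fixed at the same time. It takes, per comparison, the 10 highest and the 10 lowest log2 fold changes among called protein-coding genes with a mean of at least 5 CPM whose libraries do not overlap between the groups compared. It adds up to 4 members of each list with the lowest adjusted p, and the reference genes. A gene outside the rule is marked as chosen after its values were seen.

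Both EV groups were compared with the same PBS libraries, so 100 simulations of unchanged groups gave the correlation that shared controls alone produce. The steps were tested on simulated counts for the 12740 genes with 200 changed genes. At log2 changes of 0.5, 1 and 2 they recovered 26.9%, 73.1% and 83.3% of the changed genes for LD-F1 EVs with PBS, with 11 of 144 calls false. For LD-F1_b EVs with PBS they recovered 32.8%, 82.1% and 89.4%, with 8 of 157 calls false, and between the EV groups 47.8%, 85.1% and 89.4%, with 16 of 176 calls false. A list with planted changes was called in each of the 3 comparisons, and 0, 0 and 1 of the other lists were called. Each gene was simulated on its own, with the same spread in all groups. The simulation could therefore not show false list calls that come from correlated genes. Since the LD-F1 replicates differed more than those of the other groups, the rates of recovered genes and of false calls may not hold for these data.

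Alternatives fixed before the data were examined were RLE size factors, library totals alone, no filter, a stricter filter, limma-voom, DESeq2 1.42.0, only the groups compared, the replicate number as a block, no robust estimation, protein-coding genes alone, a minimum log2 fold change of 1, and leaving out each library in turn. A correction for gene length, with and without the block, was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The reference annotation at hand is of another build and was not used for positions.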

Results

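The data were gene counts from 6 RNA-seq libraries of mouse bone-marrow-derived macrophages: 2 after 6 h with EVs labelled LD-F1, 2 after 6 h with EVs labelled LD-F1_b, and 2 after 6 h with PBS. Libraries held 13722215 to 15277997 counts. The comparisons asked how macrophages respond to EVs of Aspergillus flavus, and whether the EV preparations differ in that response. The first principal component carried 48.9% of the variance of log2 CPM.

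LD-F1 EVs raised genes of inflammation over PBS. Cxcl2, a chemokine that attracts neutrophils, was 292-fold higher (log2 fold change 8.19 ± 0.18 SE, n = 2 per group, adjusted p = 1.13e-10), at 180 ± 16.1 CPM (SD, n = 2) against 0.609 ± 0.0302 in PBS. Csf3, which encodes the growth factor G-CSF, was 236-fold higher (7.88 ± 0.37, adjusted p = 1.02e-06), although the PBS libraries differed (0.488 ± 0.601 CPM). Nos2, the inducible nitric oxide synthase, rose 74.0-fold (6.21 ± 0.37, adjusted p = 4.14e-07), and Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose by 5.15 ± 0.26 on the log2 scale (adjusted p = 5.7e-07). In the C57BL/6NJ positions of the table, Cxcl2 lies on chromosome 5 from 95658254 to 95660321 (identifier MGP_C57BL6NJ_G0030162) and Nos2 on chromosome 11 from 82443125 to 82484262 (MGP_C57BL6NJ_G0019183). The others among the 10 highest by the rule, which asks for a mean of at least 5 CPM and no overlap of libraries, were Lcn2, an iron-siderophore-binding protein (6.52 ± 0.42), the chemerin-binding receptor gene Ccrl2 (4.43 ± 0.33), Cmpk2 (3.94 ± 0.26), the itaconate-producing enzyme gene Acod1 (3.92 ± 0.13), the glutathione-degrading enzyme gene Chac1 (3.86 ± 0.20) and Phlda1 (3.81 ± 0.23). For each of these genes both EV libraries lay above both PBS libraries.

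**Figure D1:**
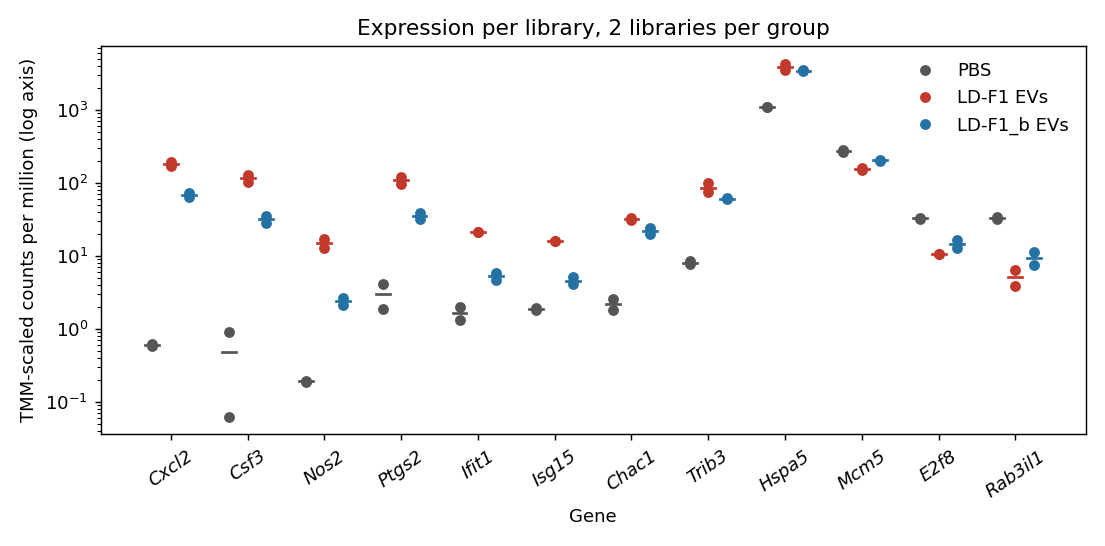
TMM-scaled CPM (log axis) of 12 genes in the 6 libraries; points are libraries and bars are means of the 2 libraries of a group. Cxcl2 averaged 0.609 CPM in PBS, 180 with LD-F1 EVs and 68.7 with LD-F1_b EVs.

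Of 11 tested proinflammatory cytokines, 10 rose with LD-F1 EVs, 0 fell and 1 did not pass (median log2 fold change 2.39; camera adjusted p = 6.09e-27). The 10 were also those adjusted over the list alone. Tnf rose by 2.39 ± 0.09 (adjusted p = 1.34e-08), Il1b by 5.30 ± 0.50 (adjusted p = 1.35e-05), Lif by 3.79 ± 0.36 and Csf1 by 2.05 ± 0.13. Il6 had 0 counts in PBS and 35 with LD-F1 EVs, at least 13.3-fold higher against a floor of 3 counts over the group. The list's median is Tnf's value and stays 2.39 with Il6 at that bound. Among 10 chemokines, 9 rose over all genes tested and 9 adjusted over the list alone (median 2.27), with Ccl3 at 2.17 ± 0.11, Cxcl10 at 3.22 ± 0.30 and Ccl4 at 1.74 ± 0.10. In the NF-kB list, 18 of 19 members rose, 19 adjusted over the list alone (median 0.82), led by Traf1 (2.80 ± 0.10), Tnfaip3 (1.96 ± 0.15) and the inhibitor Nfkbia (1.64 ± 0.08). Genes known to restrain inflammation rose too: 14 of 19 anti-inflammatory regulators, and 14 adjusted over the list alone (median 1.08), among them Il1rn, the natural antagonist of interleukin 1 (2.17 ± 0.08), Socs3 (2.09 ± 0.11) and the RNase gene Zc3h12a (2.00 ± 0.11). Of 20 immediate early and AP-1 genes, 14 rose in both counts, over all genes and adjusted over the list alone (median 0.83), with Myc at 3.24 ± 0.15 and Ier3 at 1.93 ± 0.10.

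Interferon-response genes rose with LD-F1 EVs without exception in the type I list, 25 of 25 in both counts, over all genes and adjusted over the list alone (median 1.83; camera adjusted p = 1.63e-50). Ifit1, which binds foreign RNA, rose by 3.66 ± 0.24 (adjusted p = 8.17e-07), the ubiquitin-like Isg15 by 3.07 ± 0.23, Oasl2 by 3.12 ± 0.20 and the transcription factor Irf7 by 1.82 ± 0.10. The interferon gamma list had 12 of 13 members higher and 0 lower (median 1.58), or 12 higher and 1 lower adjusted over the list alone. Its members Gbp2, a GTPase of host defence (3.34 ± 0.26), Cd274, which encodes PD-L1 (1.58 ± 0.14), and Irgm1 (0.96 ± 0.11) were among those that rose. Of 10 genes of MHC class I presentation, 5 rose, and 5 adjusted over the list alone, with Tapbp at 0.78 ± 0.08 and Tap1 at 0.90 ± 0.11; that list's call did not hold (adjusted p = 0.0964 with an estimated correlation). Without LD-F1 replicate 1, 8 rose.

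Stress-response genes formed a further group that rose with LD-F1 EVs. Of 18 genes of the integrated and unfolded protein stress response, 17 rose, and 18 adjusted over the list alone (median 1.55; camera adjusted p = 2.96e-60). Trib3 rose by 3.41 ± 0.15, the transcription factor Atf4 by 1.89 ± 0.10, Herpud1 of endoplasmic-reticulum protein degradation by 2.10 ± 0.09, and the chaperone gene Hspa5 by 1.84 ± 0.10, to 3897 CPM from 1085. In the NRF2 antioxidant list, 14 of 18 rose in both counts, over all genes and adjusted over the list alone (median 0.72), including the haem-degrading Hmox1 (1.37 ± 0.08), the cystine transporter gene Slc7a11 (1.61 ± 0.13) and Sqstm1 (1.28 ± 0.08). Of 14 p53 targets, 7 rose and 1 fell, or 7 and 2 adjusted over the list alone, with Plk2 at 2.19 ± 0.10 and Cdkn1a at 0.71 ± 0.09 (adjusted p = 0.0798 with an estimated correlation). Among 12 metal-handling genes, 6 rose, 7 adjusted over the list alone, with the iron transporter gene Slc11a2 at 1.43 ± 0.09 (adjusted p = 0.0601 with an estimated correlation). Heat shock genes were not called by camera (adjusted p = 0.39) but were by fry (adjusted p = 0.0204), and 1 of 9, Hspa1b, rose (0.91 ± 0.14).

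Genes of DNA replication fell. Of 22 S phase genes, 20 were lower with LD-F1 EVs and 0 higher, and 22 were lower adjusted over the list alone (median -0.81; camera adjusted p = 9.22e-22). Their call did not hold otherwise (adjusted p = 0.0847 with an estimated correlation). Rrm2, a subunit of the enzyme that makes deoxynucleotides, changed by -1.25 ± 0.10 (adjusted p = 3.13e-06), and the replicative helicase genes Mcm2 and Mcm4 by -0.89 ± 0.08 each. In the G2 and M phase list, 19 of 24 fell, 21 adjusted over the list alone (median -0.51), with Top2a at -0.67 ± 0.08 and Kif11 at -0.69 ± 0.10. Without PBS replicate 1 or 2, the number of lower G2 and M genes was 11 or 10. The lowest genes by the rule included E2f8, a transcriptional repressor of the cell cycle (-1.62 ± 0.15, adjusted p = 1.46e-05), the centrosomal Wdr62 (-1.58 ± 0.23) and the DNA repair gene Fanci (-1.57 ± 0.23). The lowest by the rule was Rab3il1, an exchange factor for Rab GTPases (-2.66 ± 0.23, adjusted p = 8.42e-06), while called genes outside the rule reached -4.61; Pgbd5, Opcml, the complement receptor gene C5ar2, Gpr162, Ptprf and Mns1 followed between -2.03 and -1.55.

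Sensing and effector genes moved in both directions with LD-F1 EVs. Of 15 C-type lectin receptor and signalling genes, 7 rose and 2 fell in both counts, over all genes and adjusted over the list alone (median 0.11; adjusted p = 0.0847 with an estimated correlation). Clec7a, the receptor Dectin-1 for fungal beta-glucan, rose by 1.63 ± 0.16 (adjusted p = 1.88e-05) and Clec4e, which encodes Mincle, by 1.48 ± 0.09. In the Toll-like receptor list, which was not called (camera adjusted p = 0.721), 3 of 19 rose and 2 fell, 4 and 2 adjusted over the list alone, with Cd14 at 1.23 ± 0.10 and Tlr8 at -1.41 ± 0.22. Inflammasome genes had 6 of 14 higher and 2 lower, 6 and 3 adjusted over the list alone (adjusted p = 0.108 with an estimated correlation), with Nlrp3 at 1.43 ± 0.09 and Casp4 at 1.36 ± 0.19. Of 11 M1-type markers 7 rose, 10 adjusted over the list alone, with Cd40 at 3.33 ± 0.19 (adjusted p = 0.0616 with an estimated correlation); Tnf, Nos2 and Il1b stand in other lists as well. The M2-type list was not called by camera (adjusted p = 0.414) but was by fry (adjusted p = 0.0491), with 2 of 8 higher and 2 lower, 3 and 2 adjusted over the list alone: Ccl22 and Klf4 rose (2.88 ± 0.34 and 1.24 ± 0.20), while Clec10a and Mrc1 fell (-0.68 ± 0.17 and -0.55 ± 0.15).

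Further lists were called without holding with an estimated correlation. They were the NADPH oxidase list (7 of 11 higher, 8 adjusted over the list alone, adjusted p = 0.114 with an estimated correlation), arginine and polyamine metabolism (6 of 14 in both counts, adjusted p = 0.102 with an estimated correlation) and HIF1 targets (5 of 14, 7 adjusted over the list alone, adjusted p = 0.107 with an estimated correlation). Glycolysis had 7 of 16 higher and 2 lower, 10 and 2 adjusted over the list alone (adjusted p = 0.185 with an estimated correlation). Without PBS replicates 1 and 2, 4 genes each were higher for the NADPH oxidase list, 3 and 4 for HIF1 targets and 3 and 2 for glycolysis. HIF1 targets had 9 without LD-F1 replicate 1. Among eicosanoid genes, 4 of 11 rose and 1 fell, 5 and 2 adjusted over the list alone (adjusted p = 0.111 with an estimated correlation). Matrix remodelling genes had 6 of 11 higher and 2 lower in both counts (adjusted p = 0.0847 with an estimated correlation). Their members include the NADPH oxidase subunit Cybb (0.76 ± 0.12), the ornithine decarboxylase gene Odc1 (1.33 ± 0.10), the glucose transporter gene Slc2a1 (1.05 ± 0.08) and the gelatinase gene Mmp9 (1.90 ± 0.10), which rose, and the protease inhibitor gene Timp2 (-1.54 ± 0.11), which fell. Mmp13, a collagenase gene, had 89 counts with LD-F1 EVs and 3 with PBS, a ratio of 33.8 (95% interval 11.2 to 167). Ribosomal protein genes were called upward (median 0.28, camera adjusted p = 0.00393; adjusted p = 0.614 with an estimated correlation), with 8 of 28 higher and 17 adjusted over the list alone. Without LD-F1 replicate 2 that call was lost, with a median of 0.11 and 5 genes higher, and without LD-F1 replicate 1 the median was 0.44 and 22 genes were higher; 0 were higher without either LD-F1_b replicate or PBS replicate 1, and 1 without PBS replicate 2.

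Many metabolic and housekeeping lists were not called by camera with LD-F1 EVs, although the fry test called some of them. Nuclear-encoded oxidative phosphorylation had 0 of 29 members called by edgeR in either EV comparison with PBS (median 0.06; camera adjusted p = 0.631, fry adjusted p = 0.675). The TCA cycle list had 1 of 20 higher (Acod1) and 1 lower (Ogdh, -0.35 ± 0.10), cholesterol biosynthesis 1 of 23 higher and 3 lower (Dhcr7 at -1.14 ± 0.18), LXR targets 1 of 13 higher and 2 lower (Abcg1 at -0.94 ± 0.11), and fatty acid metabolism 2 of 17 higher and 4 lower (Elovl6 at -0.87 ± 0.11). Lysosomal genes had 4 of 23 higher and 4 lower, with the transcription factors Mitf and Tfeb at 0.79 ± 0.11 and -0.99 ± 0.14. Autophagy had 5 of 20 higher and 1 lower, apoptosis 6 of 20 higher and 3 lower, ribosome biogenesis 4 of 24 higher, complement 1 of 6 higher (C3, 0.90 ± 0.11) and 1 lower (C5ar1), and phagocytosis 1 of 12 higher (Cd36) and 2 lower (Fcgr3 at -0.63 ± 0.08). Of 8 reference genes, Actb (0.60 ± 0.09), B2m (0.47 ± 0.09) and Hprt (0.40 ± 0.11) rose, and Tbp and Gusb were at -0.02 ± 0.13 and -0.04 ± 0.09. Fry called apoptosis, autophagy, ribosome biogenesis, the TCA cycle and the reference genes upward (adjusted p = 0.00522, 0.00665, 0.0381, 0.0388 and 0.035). It called fatty acid metabolism and cholesterol biosynthesis downward (adjusted p = 0.0101 and 0.035), and did not call LXR targets, lysosomal, complement or phagocytosis genes.

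Macrophage identity genes were not called as a list (camera adjusted p = 0.908), with 3 of 13 higher, among them Cebpb and Cx3cr1, and 1 lower. Among markers of other cells, the dendritic cell list had 2 of 7 higher (Xcr1 at 2.72 ± 0.28 and the interferon-induced Bst2), and the osteoclast list 3 of 8 (Mmp9, Acp5 and Dcstamp); camera called neither (adjusted p = 0.344 and 0.0572), while fry called both (adjusted p = 0.00202 and 0.012). The neutrophil list had 3 tested members, of which Lcn2 and Mmp9 rose while Csf3r was at -0.05 ± 0.38. Of 4 monocyte markers Treml4 rose (0.91 ± 0.22), of 4 genes of MHC class II presentation Cd74 rose (0.38 ± 0.10), and of 3 endothelial markers Vwf fell (-0.73 ± 0.13). The megakaryocyte chemokine Ppbp had 27 counts with LD-F1 EVs and 2 with PBS, a ratio of 15.4 (95% interval 3.86 to 133). The T and NK cell, B cell and fibroblast lists had 1, 2 and 1 tested members with 0 called by edgeR, and the mast cell and mitochondrially encoded lists had 0 tested. For the dendritic cell, Toll-like receptor, TCA cycle and osteoclast lists the median was below 0 while the mean and the test pointed up.

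In all, edgeR called 2707 of 12740 genes between LD-F1 EVs and PBS (21.2%), 1449 higher and 1258 lower, of which 351 and 194 had a log2 fold change of at least 1 in size. A fit with only the groups compared called 1947. With library totals alone the share of higher genes was 33.6% in place of 53.5%. Leaving out LD-F1 replicate 1 gave 4484 calls, and leaving out PBS replicate 1 or 2 gave 1203 or 1279.

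LD-F1_b EVs raised many of the same kinds of genes over PBS, again led by Cxcl2 (111-fold, 6.80 ± 0.19 SE on the log2 scale, n = 2 per group, adjusted p = 1.54e-09) and Csf3 (64.9-fold, 6.02 ± 0.40, adjusted p = 2.19e-05). Lcn2 rose by 5.62 ± 0.45, Ccrl2 by 3.88 ± 0.34, Nos2 by 3.58 ± 0.46, Ptgs2 by 3.54 ± 0.26 and Acod1 by 2.83 ± 0.13. The other genes among the 10 highest by the rule were Chac1 (3.31 ± 0.20, adjusted p = 1.47e-06), Trib3 (2.90 ± 0.15) and Myc (2.62 ± 0.15). Chac1 lies on chromosome 2 from 126123209 to 126126361 in the C57BL/6NJ positions of the table.

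The stress-response list had 17 of 18 genes higher with LD-F1_b EVs in both counts, over all genes and adjusted over the list alone (median 1.34; camera adjusted p = 2.79e-76): Herpud1 rose by 1.93 ± 0.09, Hspa5 by 1.65 ± 0.10 and Atf4 by 1.58 ± 0.10. Of 11 proinflammatory cytokines, 7 rose, and 8 adjusted over the list alone (median 1.83), with Tnf at 1.83 ± 0.09 and Il1b at 3.88 ± 0.55. Chemokines had 8 of 10 higher, 9 adjusted over the list alone (median 1.11), with Ccl3 at 1.54 ± 0.11, while Cxcl10 was at 0.95 ± 0.35 (adjusted p = 0.108). The NF-kB list had 14 of 19 higher, 18 adjusted over the list alone (median 0.63), with Traf1 at 1.83 ± 0.10, and 9 higher without LD-F1_b replicate 2. Anti-inflammatory regulators had 11 of 19 higher, or 14 higher and 1 lower adjusted over the list alone (median 0.76), with Il1rn at 1.54 ± 0.08, and immediate early genes 11 of 20, 14 adjusted over the list alone (median 0.72).

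Of 25 type I interferon-response genes, 20 rose with LD-F1_b EVs, and 23 adjusted over the list alone (median 0.84; adjusted p = 0.0656 with an estimated correlation), with Ifit1 at 1.65 ± 0.26, Isg15 at 1.27 ± 0.25 and Irf7 at 0.93 ± 0.10. That number was 7 and 11 without LD-F1_b replicates 1 and 2, and 11 and 9 without PBS replicates 1 and 2. The interferon gamma list had 6 of 13 higher, 7 adjusted over the list alone (median 0.71; adjusted p = 0.0601 with an estimated correlation), with Gbp2 at 1.91 ± 0.28 and Irgm1 at 0.22 ± 0.11 (adjusted p = 0.241). It had 3 higher without any 1 of the LD-F1_b or PBS libraries. The NRF2 list had 10 of 18 higher, 16 adjusted over the list alone (median 0.48; adjusted p = 0.0601 with an estimated correlation), with Hmox1 at 0.81 ± 0.08, and 6 were higher without PBS replicate 2. Clec7a and Clec4e were among 7 of 15 C-type lectin genes that rose (1.28 ± 0.16 and 1.04 ± 0.09), with 0 lower; the count was the same adjusted over the list alone (adjusted p = 0.073 with an estimated correlation) and 4 without any 1 of the LD-F1_b or PBS libraries.

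S phase genes fell with LD-F1_b EVs as well: 14 of 22 were lower and 0 higher, and 19 were lower adjusted over the list alone (median -0.51; adjusted p = 0.111 with an estimated correlation). Rrm2 changed by -0.75 ± 0.10 and Mcm2 by -0.59 ± 0.08. The number of lower S phase genes was 3 and 7 without LD-F1_b replicates 1 and 2, and 5 and 7 without PBS replicates 1 and 2. In the G2 and M phase list 6 of 24 fell, 14 adjusted over the list alone (median -0.30; adjusted p = 0.0601 with an estimated correlation), including Kif11 at -0.50 ± 0.10. That number was 15 without either LD-F1 library and 0 by edgeR without any 1 of the LD-F1_b or PBS libraries. Rab3il1 was again the lowest gene by the rule (-1.79 ± 0.22, adjusted p = 0.000262), while called genes outside it reached -3.54. The rule's other lowest genes were the phosphatase-domain gene Pald1 (-1.41 ± 0.14), Ttc39a (-1.33 ± 0.30), the nucleoside transporter gene Slc29a3 (-1.20 ± 0.26), E2f8 (-1.16 ± 0.15), Aunip, Atad5, C5ar2, Celsr1 and Alms1. The calls of Ttc39a and Slc29a3 were lost without any 1 of the LD-F1_b or PBS libraries, that of C5ar2 without LD-F1_b replicate 2, that of Alms1 without LD-F1_b replicate 1 or PBS replicate 1, and that of Celsr1 without either LD-F1_b library or PBS replicate 1. Over the 18 alternatives their adjusted p ranged from 2.04e-06 to 0.202 (Ttc39a), 2.55e-09 to 0.166 (Slc29a3), 3.86e-06 to 0.0513 (C5ar2), 2.78e-05 to 0.0557 (Alms1) and 0.000834 to 0.28 (Celsr1).

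Other lists called upward with LD-F1_b EVs did not hold with an estimated correlation. M1-type markers had 5 of 11 higher, 6 adjusted over the list alone (adjusted p = 0.0798 with an estimated correlation). Matrix remodelling had 6 of 11 higher and 2 lower, 7 and 2 adjusted over the list alone (adjusted p = 0.0601 with an estimated correlation), with the elastase gene Mmp12 at 1.47 ± 0.15; Mmp13 had 31 counts against 3 in PBS, a ratio of 11.2 (95% interval 3.49 to 57.1). Metal handling had 5 of 12 higher and p53 targets 7 of 14 higher and 1 lower (adjusted p = 0.0622 and 0.0819 with an estimated correlation). HIF1 targets had 4 of 14 higher, eicosanoid genes 4 of 11 higher and 1 lower, and glycolysis 6 of 16 higher (adjusted p = 0.107, 0.108 and 0.161 with an estimated correlation). Counts were 4 of 11 higher for the NADPH oxidase list, 5 of 14 for arginine metabolism, 3 of 10 for MHC class I and 3 of 14 with 1 lower for inflammasome genes (adjusted p = 0.14, 0.161, 0.136 and 0.149 with an estimated correlation). Without LD-F1 replicates 1 and 2 these numbers were 7 each for the NADPH oxidase list and MHC class I, 10 and 11 for glycolysis, 9 and 10 for HIF1 targets and 5 each for inflammasome genes. M1-type markers had 8 without LD-F1 replicate 2. Glycolysis had 1 without any 1 of the LD-F1_b or PBS libraries, and MHC class I 0 by edgeR. Without LD-F1_b replicates 1 and 2 and PBS replicates 1 and 2, in that order, the numbers were 2, 2, 1 and 2 for eicosanoid genes and 3, 2, 2 and 3 for HIF1 targets. They were 4, 2, 3 and 2 for arginine metabolism, 3, 4, 4 and 3 for metal handling and 5, 3, 5 and 4 for p53 targets. Ribosomal proteins had a median of 0.23, with 0 of 28 called by edgeR and 21 without either LD-F1 replicate (adjusted p = 0.599 with an estimated correlation). Ppbp had 25 counts against 2 in PBS, a ratio of 13.5 (95% interval 3.37 to 118).

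EdgeR called 1398 genes between LD-F1_b EVs and PBS, 820 higher and 578 lower, of which 183 and 41 had a log2 fold change of at least 1 in size. A fit with only the groups compared called 3117. The main fit shares 1 spread per gene among groups whose replicates differed unequally (SD of the log2 difference 0.268 for LD-F1, 0.153 for LD-F1_b and 0.119 for PBS). Fewer called genes with LD-F1_b EVs, here and within lists, therefore do not by themselves show a weaker response. In the main fit the share of higher genes was 58.7%, and it was 41.7% with library totals alone. It was above 58.7% when any 1 of the LD-F1_b or PBS libraries was left out. Without LD-F1_b replicate 1 or 2 the number of calls was 378 or 419, without PBS replicate 1 or 2 it was 395 or 466, and without LD-F1 replicate 1 or 2 it was 3099 or 3122.

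**Figure D2:**
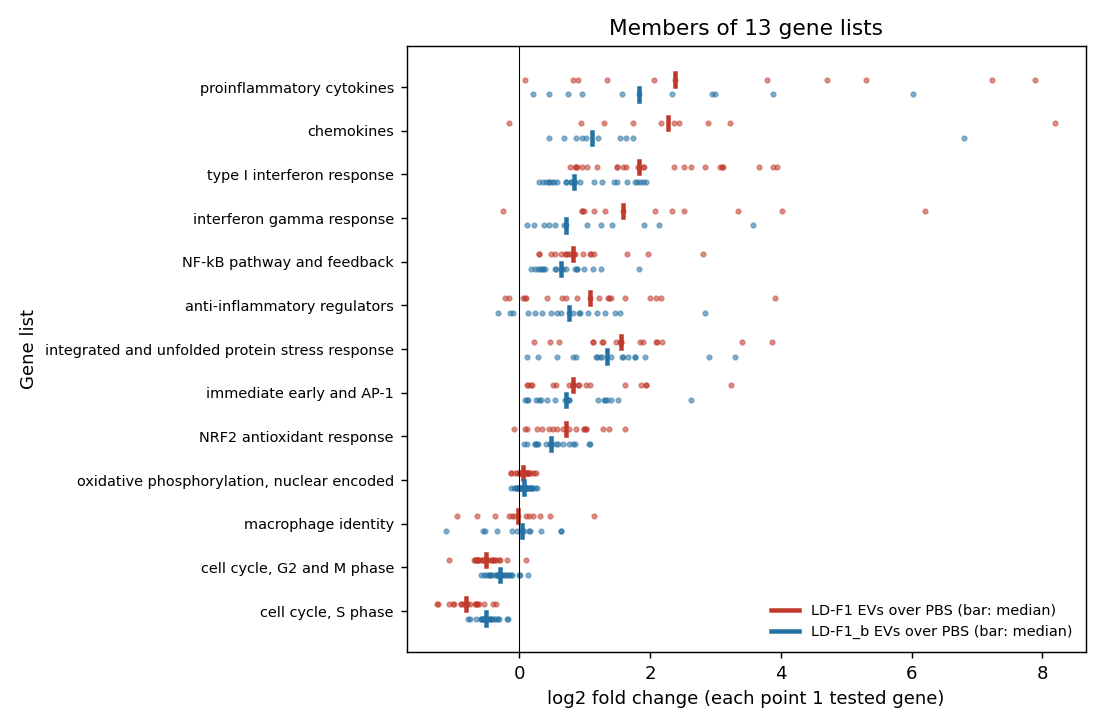
Log2 fold changes over PBS (horizontal axis) of the tested members of 13 gene lists; each point is a gene and each bar the list's median, for LD-F1 EVs (red) and LD-F1_b EVs (blue). The type I interferon medians were 1.83 and 0.84, and the stress-response medians 1.55 and 1.34.

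Compared directly, LD-F1_b EVs left inflammatory and interferon-response genes below their level with LD-F1 EVs. Nos2 was the lowest (log2 fold change -2.63 ± 0.25 SE, n = 2 per group, adjusted p = 0.000965), at 2.39 ± 0.332 CPM (SD, n = 2) against 14.9 ± 2.82. The other lowest genes by the rule were Cmpk2 (-2.04 ± 0.22), Ifit1 (-2.01 ± 0.21), Csf3 (-1.86 ± 0.22), Isg15 (-1.80 ± 0.20), Ptgs2 (-1.61 ± 0.19), the chemokine gene Ccl5 (-1.59 ± 0.20), Gbp2 (-1.43 ± 0.22), Cxcl2 (-1.39 ± 0.10) and Oasl2 (-1.34 ± 0.17). Of the 54 genes that edgeR called, 52 were lower with LD-F1_b EVs and 2 higher. That split was less one-sided in some other fits, with 137 lower and 48 higher without a filter. All 52 were higher with LD-F1 EVs than with PBS, and 46 of them were also higher with LD-F1_b EVs than with PBS; the comparisons share libraries. The 2 higher genes were Timp2 (0.71 ± 0.11, adjusted p = 0.0134) and Mmd (0.55 ± 0.10, adjusted p = 0.0418), both lower with LD-F1 EVs than with PBS. Neither passed without any 1 PBS or LD-F1_b library, and their adjusted p over the 18 alternatives ranged from 3.46e-05 to 0.361 and from 0.000317 to 0.626.

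Among type I interferon-response genes, 13 of 25 were lower with LD-F1_b EVs than with LD-F1 EVs, and 23 adjusted over the list alone (median -1.03; camera adjusted p = 4.2e-82), with Irf7 at -0.89 ± 0.10 and Ifi204 at -1.03 ± 0.11. Chemokines had 5 of 10 lower, 9 adjusted over the list alone (median -0.68), including Cxcl10 at -2.26 ± 0.28 (adjusted p = 0.00368) and Ccl3 at -0.63 ± 0.10. The interferon gamma list had 3 of 13 lower, or 12 lower and 1 higher adjusted over the list alone (median -0.74), with Irgm1 at -0.74 ± 0.11. Proinflammatory cytokines had 2 of 11 lower, Csf3 and Tnf (-0.56 ± 0.08), and 8 adjusted over the list alone (median -0.56). Anti-inflammatory regulators had 4 of 19 lower, 9 adjusted over the list alone (median -0.31), among them Acod1 (-1.08 ± 0.12) and Hmox1 (-0.56 ± 0.08). NF-kB genes had 2 of 19 lower, Traf1 (-0.98 ± 0.09) and Nfkbia (-0.51 ± 0.08), and 8 adjusted over the list alone (median -0.24). Without LD-F1 replicates 1 and 2 the numbers of lower genes were 8 and 5 for chemokines, 6 and 5 for interferon gamma and 5 and 2 for cytokines. They were 9 and 8 for anti-inflammatory regulators and 6 each for NF-kB. NF-kB had 1 without either PBS library. Without either LD-F1_b library edgeR called 0 in each of these lists, since it called 0 of all genes.

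The stress-response list had 0 of 18 genes called by edgeR between the EV groups and 7 lower adjusted over the list alone (median -0.23; camera adjusted p = 2.91e-08, adjusted p = 0.214 with an estimated correlation). Without LD-F1 replicate 1, 8 were lower, and without LD-F1 replicate 2 the median was -0.12. Hspa5 was at -0.19 ± 0.10 (adjusted p = 0.631), Herpud1 at -0.17 ± 0.09 and Atf4 at -0.31 ± 0.09. S phase genes had 0 of 22 called and 16 higher adjusted over the list alone (median 0.32; adjusted p = 0.107 with an estimated correlation), with Rrm2 at 0.50 ± 0.10 (adjusted p = 0.0549); 10 and 9 were higher without LD-F1 replicates 1 and 2. G2 and M genes had 0 of 24 called and 2 higher adjusted over the list alone (median 0.20), and 5 higher without LD-F1 replicate 1. Other lists called downward did not hold: M1-type markers with 5 of 11 lower, NRF2 with 2 of 18, immediate early genes with 1 of 20 and arginine metabolism with 2 of 14 (adjusted p = 0.0601, 0.0798, 0.0798 and 0.0881 with an estimated correlation). Nor did MHC class I, the NADPH oxidase list and p53 targets, with 1 of 10, 1 of 11 and 1 of 14 lower (adjusted p = 0.107, 0.18 and 0.136 with an estimated correlation), or metal handling, inflammasome genes and HIF1 targets, with 0 called by edgeR and 2 of 12, 3 of 14 and 2 of 14 lower adjusted over the list alone (adjusted p = 0.106, 0.126 and 0.264 with an estimated correlation). Without LD-F1 replicates 1 and 2, 11 and 7 genes were lower for NRF2, 8 and 4 for immediate early genes, 5 and 3 for arginine metabolism and 4 and 2 for MHC class I. They were 4 and 1 for HIF1 targets, 3 and 2 for p53 targets and for metal handling, 3 and 1 for inflammasome genes and 2 each for the NADPH oxidase list. Without either PBS library 1 was lower for NRF2 and for arginine metabolism, and 0 by edgeR for immediate early genes and MHC class I.

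At an unadjusted p under 0.05 edgeR had 1119 genes between the EV groups. DESeq2 and limma-voom called 97 and 70, of which 15 and 2 were higher with LD-F1_b EVs. When either LD-F1 library was left out, the calls of edgeR were less one-sided than in the main fit. Without LD-F1_b replicate 1 or 2, edgeR called 0 genes, with 646 or 761 at an unadjusted p under 0.05, and all 54 kept their sign and that unadjusted p; without LD-F1 replicate 1 or 2 it called 1111 or 337, the 54 among them each time.

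Across the 12740 genes the log2 fold changes of the EV groups over PBS correlated (Pearson's r = 0.79, Spearman's rho = 0.79; genes are not independent replicates). Shared controls alone gave a mean r of 0.484 and at most 0.55 in 100 simulations. The covariance was 0.235, against a simulated 0.0423, a difference of 0.193. Of the genes called, 772 were higher and 534 lower in both comparisons, and 0 were called by edgeR in opposite directions. With a PBS library of its own for each EV group, r of the log2 CPM differences was 0.604 with PBS replicate 1 for LD-F1 and 0.61 with PBS replicate 2 for it. This split was chosen after the results were seen. With it 292 and 315 genes were higher in both comparisons, where independent calls would share 17.0 and 17.8, and 87 and 122 lower, where they would share 4.07 and 5.49. The slope of the LD-F1_b changes on the LD-F1 changes was 0.64.

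**Figure D3:**
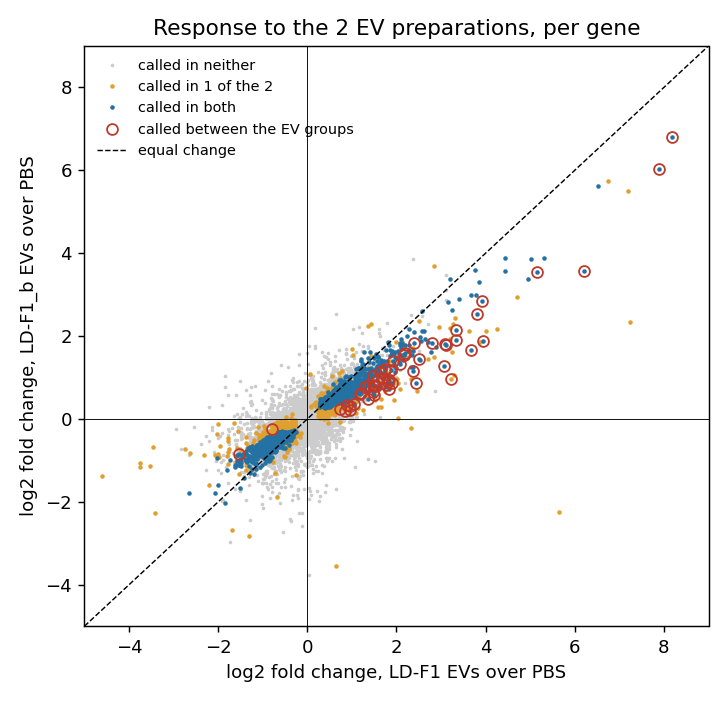
Log2 fold change over PBS per gene with LD-F1 EVs (horizontal axis) and LD-F1_b EVs (vertical axis); colours give the comparisons in which a gene was called, circles the 54 genes called between the EV groups, and the dashed line equal change. The circled genes lie mostly below the line on the right, where LD-F1 EVs raised them more.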

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

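The effects of the EV groups were compared in a direct test, planned before the data were examined, and the results that differ are given here; the tests of explanations for them, for the LD-F1 replicates and for the S phase genes were chosen after the results were seen. Between LD-F1_b and LD-F1 EVs, 54 genes and 19 gene lists passed the test of the difference itself. The lists that hold with an estimated correlation had median log2 fold changes of -0.56 (proinflammatory cytokines), -0.68 (chemokines), -0.24 (NF-kB), -1.03 (type I interferon), -0.74 (interferon gamma), -0.31 (anti-inflammatory regulators) and 0.20 (G2 and M phase). The genes named by the rule were Timp2 at 0.71 and Mmd at 0.55, and below 0 Nos2 at -2.63, Cmpk2 at -2.04, Ifit1 at -2.01, Csf3 at -1.86, Isg15 at -1.80, Ptgs2 at -1.61, Ccl5 at -1.59, Gbp2 at -1.43, Cxcl2 at -1.39 and Oasl2 at -1.34.

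The 54 genes form the first pattern. A trend with gene length as the whole cause is argued against, since 53 of them were still called once it was removed. The 54 genes stayed called when either LD-F1 library was left out, but this cannot decide on a lone LD-F1 library. Such a fit takes the spread of LD-F1 from the other groups, whose replicates differed less. Without LD-F1_b replicate 1 or 2 the calls end (smallest adjusted p 0.0579 and 0.11) as the median SE of the 54 genes rises from 0.11 to 0.15 each time, against 0.10 without either LD-F1 library. Meanwhile the median share of each fold change kept was 1.01 and 0.991 (quartiles 0.961 to 1.08 and 0.928 to 1.04). The fold changes of these 54 genes were thus of similar size with either LD-F1_b library alone. Calling favours genes whose replicates agree, so shares near 1 are partly built in and lend no further support. One common weakening of the whole response stays open. The share of the LD-F1 response kept with LD-F1_b EVs is the ratio of the lists' mean log2 fold changes over PBS. In 11 lists it ran from 49.7% (type I interferon, 45.5% to 52.2% without any 1 library) to 85.8% (stress response, 81.7% to 90.7%). The others were at 53% (interferon gamma), 57.2% (G2 and M phase), 60.4% (S phase), 65.5% (cytokines), 67.3% (chemokines), 70.6% (anti-inflammatory regulators), 70.8% (NF-kB), 73.3% (NRF2) and 81.6% (immediate early genes). Ratios of medians order the lists differently, with chemokines at 49.0% and cytokines at 76.7%, over a range of 45.0% to 87.0%; the cytokine mean includes Il6, which had 0 counts in PBS. A common share of 0.7 was chosen from these data as the one that the fry test opposed least. Against it, 0 of the 24 lists called for LD-F1 EVs departed at an adjusted p under 0.05 and 7 at an unadjusted one. The smallest adjusted p of fry was 0.1, and 0.079 with limma-voom at its own best share. Since the share was chosen in this way, the lack of departures does not speak for a common weakening. A difference in what the EV preparations carry, or in their strains, may explain the pattern and stays open as an untested biological hypothesis, as does unequal potency per 20 µg.

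The second pattern is the difference between the LD-F1 replicates along gene length, where replicate 2 minus replicate 1 had a median log2 of 0.18 among the shortest genes and -0.18 among the longest, with genes split at the quartiles of length. Gene length accounted for 28.8% of the variance of that difference, but removing it lowered its SD only from 0.268 to 0.226, against 0.118 between PBS and 0.147 between LD-F1_b replicates after the same step, so the length trend is not the whole difference. A stronger response in one replicate, a biological explanation, is argued against as the whole difference, since the LD-F1_b log2 fold changes accounted for 5.46% of it. A stronger response as a part of it is not excluded. On the first principal component the LD-F1 replicates lay at -22.0 and -31.5 and the PBS libraries at 35.9 and 34.9. The stress-response median was 1.67 without LD-F1 replicate 1 and 1.39 without replicate 2, and that of chemokines 2.28 and 2.24. Other medians leaned the other way, with type I interferon at 1.76 and 1.89, cytokines at 2.35 and 2.42 and the S phase at -0.77 and -0.87 in that order. RNA integrity and library preparation are not given per library in the sources used here and stay open.

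The third pattern is the lower level of S phase genes with both EV preparations, whose call as a list did not hold with an estimated correlation (adjusted p = 0.0847 and 0.111). Gene length as the cause is argued against, although fold changes over PBS did follow length across 7759 genes (Spearman's rho = -0.28 and -0.29 for LD-F1 and LD-F1_b EVs): with the length correction, all 20 members called for LD-F1 EVs and all 14 called for LD-F1_b EVs were kept. A lone EV library is argued against by the list's median, of which a share of at least 0.895 was kept without any 1 EV library, although fewer members were called without an LD-F1_b library. Fewer cycling cells, or less of these transcripts per cycling cell, may explain the pattern as hypotheses, and counts over all cells of a culture do not separate them.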

How the results depend on the processing

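The length correction was chosen after seeing the data, and the other alternatives were planned. With only the groups compared, calls numbered 1947 for LD-F1 EVs and 3117 for LD-F1_b EVs with PBS. The main fit had the reverse order, 2707 and 1398, so which EV group had more calls depended on the fit. For LD-F1 EVs with PBS, calls numbered 545 with a log2 fold change of at least 1 and 1203 to 4484 without 1 library. For LD-F1_b EVs with PBS they were 224 with that minimum, 3117 with only the groups compared, and 378 to 3122 without 1 library. Between the EV groups they were 19 with that minimum, 185 without a filter, 111 with the length correction and 112 with it and the replicate block, 30 with only the groups compared, 97 with DESeq2, and 0 to 1111 without 1 library. The minimum works by construction, and without either LD-F1_b library the median SE of the 54 genes rose from 0.11 to 0.15. The LD-F1 libraries are not among the groups compared in LD-F1_b EVs with PBS, but they enter the shared spread of the main fit. Their replicates differed most (SD of the log2 difference 0.268, against 0.153 for LD-F1_b and 0.119 for PBS). The rise from 1398 to 3117 calls with only the groups compared is what a smaller spread would give. The other causes were not tested. Of the 54 genes, DESeq2 and the length correction each kept 53 and limma-voom 54; DESeq2 lost Csf3, at the same -1.86 (adjusted p = 0.959; 4.81e-39 to 0.959 over its 18 alternatives). Gene list calls fell from 67 to 23 with an estimated correlation. The correlation of the EV responses was 0.572 without a filter and 0.675 to 0.831 without 1 library, and the overlap 1306 genes and 372 to 2611 without 1 library. Between the EV groups the median of the oxidative phosphorylation list was -0.16 without LD-F1 replicate 1 and 0.13 without LD-F1 replicate 2, and that of the ribosomal proteins -0.24 and 0.12, so both lists turned with the LD-F1 library left out; the cause was not tested.

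No label ties same-numbered replicates of different groups to a shared mouse, day or batch, so the numbers are not taken as pairs. Across genes their deviations correlated at r = -0.006 between PBS and LD-F1, -0.061 between PBS and LD-F1_b and 0.19 between the EV groups. The last value leaves a factor shared by same-numbered EV libraries open. With the replicate number as a block the calls were 2706, 1357 and 52, of which 51 were among the 54. RLE size factors, library totals alone, the stricter filter, protein-coding genes alone and no robust estimation kept each total within 1.5 times. With library totals alone, though, lower calls were 1934 in place of 1258 for LD-F1 EVs and 880 in place of 578 for LD-F1_b EVs. Higher calls between the EV groups were 5 in place of 2, and 7 with protein-coding genes alone. They were 15 with DESeq2, 19 with the length correction and 48 without a filter, and more still when either LD-F1 library was left out. A fit without 1 library assumes that the remaining library of that group varies like the other groups. In simulations with the same spread in all groups, 26.9% of genes changed by 0.5 on the log2 scale were recovered for LD-F1 EVs with PBS. Small changes that were not called are therefore not shown to be absent.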

Other observations

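The genes in these paragraphs lie outside the lists or carry no symbol in the table, and were chosen after their values were seen. Of the 2707 genes called for LD-F1 EVs, 2398 were in none of the lists. The genes named here are single examples and were not tested as groups. Cth, an enzyme of cysteine synthesis, rose by 2.55 ± 0.23 with LD-F1 EVs and 1.87 with LD-F1_b EVs (log2, SE, n = 2 per group), the amino acid transporter gene Slc1a4 by 1.88 and 1.54, the mitochondrial PEP carboxykinase gene Pck2 by 1.53 and 1.22, and the secreted folding factors Creld2 and Manf by 1.76 and 1.59 with LD-F1 EVs and by 1.66 and 1.49 with LD-F1_b EVs. The protease inhibitor gene Slpi rose by 2.28 and 1.65 and the acute-phase gene Saa3 by 2.07 and 1.37. Soat2, a cholesterol-esterifying enzyme gene, rose by 2.52 and 1.97. Lower genes included the cannabinoid receptor gene Cnr2 (-1.48 and -1.07) and the cohesin acetyltransferase gene Esco2 (-1.51 and -1.02).

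Of 1536 tested entries without a symbol, 167 were called for LD-F1 EVs, and some have a description in the table. The entry described as NF-kappa-B inhibitor zeta, on chromosome 16 from 56432165 to 56461834 in the C57BL/6NJ positions, rose by 2.57 ± 0.14 (adjusted p = 3.12e-07) and by 2.11 with LD-F1_b EVs. Entries described as vascular endothelial growth factor A (1.77 and 1.27) and CCAAT/enhancer-binding protein delta (1.40 and 1.01) rose as well. Those described as claspin (-1.53 and -1.02) and UHRF1 (-1.36 and -0.86), both of DNA replication, fell. Of 527 tested loci assembled from the reads, 70 were called for LD-F1 EVs, 31 for LD-F1_b EVs and 1 between the EV groups.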
